A study of Mus musculus with 4 samples.

How the data were processed

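RNA was extracted with Trizol, treated with DNase and sent by the submitters to BGI for mRNA enrichment, routine library preparation and sequencing, per the labels' protocols and the series design text. The tissue is given as GTN muscle of C57BL/6 mice, and the 4 samples fall into 2 genotype groups, Con-TD (libraries F and G) and MCK-TD (libraries A and B). The labels expand none of these abbreviations and name no altered gene, so a check of a targeted gene against the labels was not possible. They do not say whether the libraries come from separate animals, and give no batch or date.

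The deposited table holds one FPKM value per gene and library, computed by the authors (fragments per kilobase of transcript scaled by the mapped fragments of the library). STAR, Cufflinks and the mouse build mm9 are named in the submitters' processing notes, without versions. The role of each tool and the gene annotation are not given in the sources used here. Text notes beside gene names, deposited with the table, carry no stated reference and were not used here. The table has 37305 rows and 33923 distinct gene symbols, and some symbols stand on more than 1 row. Date-converted symbols (25 rows) were left under the names the table gives them. Symbols were looked up in annotation tables of GRCm38, another build than that of the deposited values, only for names, gene types and transcript lengths, so coordinates are not given. Of the rows tested, 94.1% had a symbol in those tables.

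Counts cannot be recovered from these FPKM values, and the absolute depth is unknown. The value of a single fragment, read from the most frequent ratio between libraries over genes with FPKM under 0.2, puts the depth of Con-TD G, MCK-TD A and MCK-TD B at 0.934, 0.955 and 0.945 of that of Con-TD F. FPKM sums were 2725173 in Con-TD F, 2762335 in Con-TD G, 1899175 in MCK-TD A and 2068375 in MCK-TD B. Most of each sum came from mitochondrial tRNA rows (1716662, 1773160, 963238 and 1144887), whose short lengths inflate FPKM. Without mitochondrial and small RNA rows, the 20 most abundant genes made up 48.3%, 43.8%, 36.0% and 38.3% of the sum.

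An exact 0 in this table can be a failed estimate. The mitochondrial genes mt-Co1, mt-Co3, mt-Atp6 and mt-Atp8, which every muscle fibre transcribes, are at 0 in all 4 libraries. Genes with a 0 are therefore described as listed at 0, with each library's value. Of the rows tested, 373 were at exactly 0 in at least 1 library, and 274 of these were small RNA genes. Rows of near-identical gene copies (multigene families, pseudogenes) share fragments and are uncertain.

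Values were used as log2(FPKM + 1), so that a log2 change understates the change of genes with low FPKM. Rows with a mean FPKM of at least 1 over the 4 libraries were kept, 12474 rows. Limma 3.58.1 under R 4.3.3 fitted the genotype group alone, with 2 residual degrees of freedom, and its moderated test with an intensity trend was taken two-sided with Benjamini-Hochberg adjustment. A gene is called at an adjusted p under 0.05. Changes are MCK-TD minus Con-TD. Group values are mean FPKM ± SD over the 2 libraries of a group, and fold values are ratios of these means. The deposited values were not rescaled for this test.

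Gene lists (40 for pathways or functions and 13 for cell type markers) were fixed before the data were examined, and 49 had at least 3 members among the rows tested. Germline, lymphocyte, skin and sex-linked lists had fewer. Limma's camera with a preset inter-gene correlation of 0.01 compared each list with all other genes, with Benjamini-Hochberg adjustment over the lists tested. Camera's direction is relative to the other genes, so a list whose median lies a little above 0 can be placed below them. Camera was repeated with an estimated correlation and on ranks, and limma's fry tested whether members move, on balance, one way.

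The genes named in the text follow a rule fixed before the data were examined. It takes up to 12 genes with the largest positive and up to 12 with the largest negative log2 change among calls whose groups do not overlap, leaving out predicted, clone-named, small RNA and mitochondrial genes. For each list it takes up to 4 members, those past the threshold with the largest change first, then those with the smallest p. Any other gene is named after its values were seen, and is marked so. Some list members that this rule takes are not reported here.

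The fit was tested on simulated data with the 12474 rows of this comparison and known changes. It called 36% of genes changed by 0.5 on the log2 scale, 98.0% of those changed by 1 and 100% of those changed by 2, with the right sign. Unchanged genes made up 3.12% of those calls. The simulation made 192 calls, against 3837 in the real data. It changed few rows, none of low abundance, and drew independent errors from the variance model that the fit assumes. These shares therefore check the method under its own assumptions and are not the power or error rate of the real comparison. Alternatives tried were other pseudocounts, filters, scalings and variance models, other thresholds, other list tests, and leaving out each library in turn. Further alternatives chosen after seeing the data were protein-coding symbols only, rows without a 0, 1 row per symbol, and scaling on the sum without mitochondrial and small RNA genes and the 20 most abundant others. Tables and figures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.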

Results

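Transcript abundance was measured by RNA sequencing of mouse muscle, labelled GTN muscle, from 2 genotype groups called Con-TD and MCK-TD, with 2 libraries in each. The abundance of a gene is its deposited FPKM, a fragment count scaled by transcript length and library size. The relative depth of the 4 libraries lay between 0.934 and 1, and the absolute depth is unknown. Across genes, which are not independent replicates, Pearson's r of log2 values was 0.953 between the Con-TD libraries and 0.946 between the MCK-TD libraries. Between libraries of different groups it was 0.881 to 0.904. The labels do not state that the libraries came from separate animals, so p-values measure only the spread between these libraries, which may be technical. An unrecorded batch and the genotype cannot be told apart in this design.

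The comparison of MCK-TD with Con-TD asks which transcripts differ between the genotypes. Sln, encoding sarcolipin, a small regulator of the sarcoplasmic reticulum calcium pump, rose from 5.57 ± 2.22 FPKM in Con-TD to 657 ± 439 in MCK-TD (mean ± SD, n = 2 per group), a 118-fold difference (log2 change 6.51, SE 0.57, limma adjusted p = 0.00853). Uchl1, a ubiquitin hydrolase, rose 104-fold to 108 ± 67.8 FPKM, and Serpinb1a, a serine protease inhibitor, rose 73.4-fold to 127 ± 10.3. Ankrd1, an ankyrin-repeat protein of stressed muscle, rose 56.5-fold to 292 ± 169 FPKM. Myl4, the embryonic and atrial myosin light chain, rose from 12.4 ± 2.33 to 517 ± 55.3 FPKM. Among falling genes, the carboxylesterase Ces1d went from 40.1 ± 6.94 to 0.688 ± 0.0538 FPKM (log2 change -4.60, SE 0.15, limma adjusted p = 0.00392).

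The remaining genes named by size covered several functions. Those that rose were the metallothionein Mt3 (log2 change 4.55, SE 0.22), the zinc finger protein Hivep3 (4.12, SE 0.14), the GTPases Rhod (4.06, SE 0.49) and Rrad (4.05, SE 0.23), the collagen cross-linking enzyme Lox (4.03, SE 0.19), the small heat shock protein Hspb7 (4.01, SE 0.27) and Mustn1 (3.97, SE 0.33). Hspb7 and Mustn1 were abundant in MCK-TD, at 925 ± 192 and 711 ± 161 FPKM, against 57.2 ± 16.9 and 45.5 ± 17.8 in Con-TD. Those that fell included Fbp2, the muscle fructose bisphosphatase, from 42.5 ± 3.65 to 3.38 ± 1.32 FPKM, and Pcx, pyruvate carboxylase, from 44.9 ± 7.72 to 5.19 ± 0.193 FPKM. Myl3, the slow and ventricular myosin light chain, fell from 174 ± 63.7 to 19.9 ± 2.72 FPKM, and the water channel Aqp4 fell from 8.75 ± 1.41 to 0.242 ± 0.0742. Smox, spermine oxidase (log2 change -2.89, SE 0.39), D0H4S114 (-2.77, SE 0.12), the cadherin Cdh4 (-2.61, SE 0.35), the ciliary neurotrophic factor receptor Cntfr (-2.52, SE 0.11), the arginine deiminase Padi2 (-2.51, SE 0.31) and Fgfbp1 (-2.45, SE 0.21) fell as well. Mup10 also fell (-2.88, SE 0.37), but it belongs to a family of near-identical genes and its value is uncertain. Limma adjusted p-values of these 24 genes ranged from 0.00189 for Serpinb1a to 0.0142 for Cdh4.

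**Figure D1:**
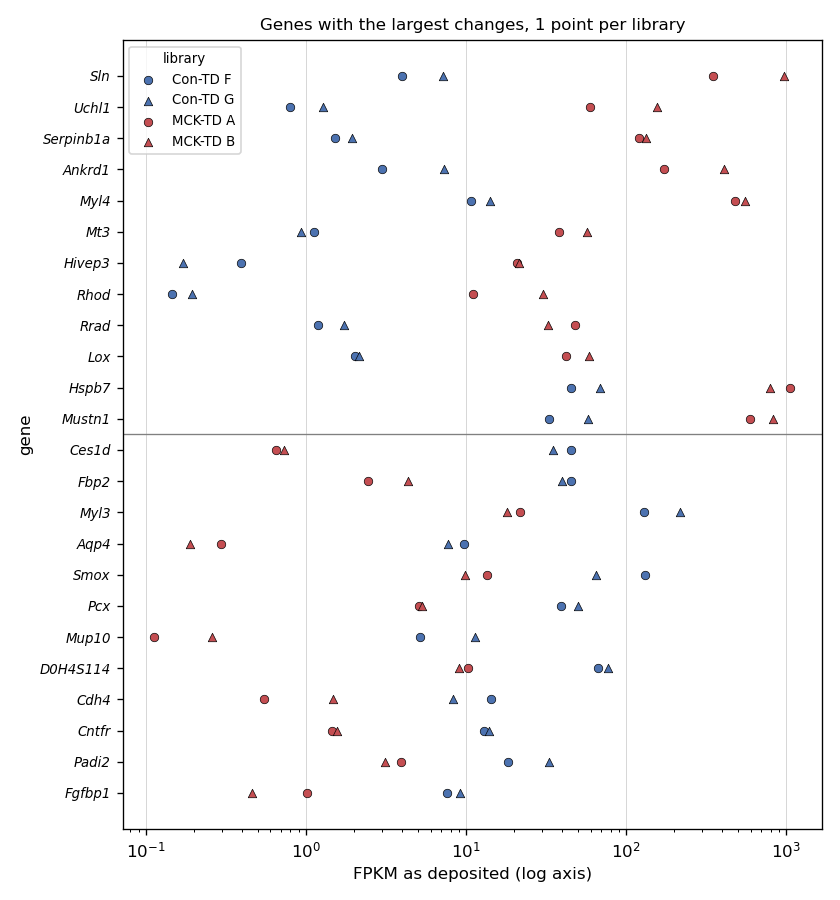
FPKM of the 24 genes named by size on a log axis, with 1 point for each library (blue, Con-TD; red, MCK-TD), genes that rose above the grey line and genes that fell below it. For each gene the 2 MCK-TD libraries lie on one side of the 2 Con-TD libraries; for Sln they are 347 and 968 FPKM against 4 and 7.14.

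Over all genes, 3837 of 12474 rows (30.8%) were called by limma's moderated test with Benjamini-Hochberg adjustment, 3033 higher and 804 lower in MCK-TD. A log2 change of at least 1 was reached by 1221 of the higher and 254 of the lower calls. The groups did not overlap for 8983 rows (72%). Chance gives 33.3% for a single row, but rows of a library can shift together and separate the groups for most rows. The share is therefore not a test. Relative to the deposited scale the median change of all rows was 0.22, and the balance of directions depended on scaling. Higher calls were 79.0% as deposited, 54.8% with median of ratios scaling (1833 higher, 1510 lower), 48.8% with quantile normalization (1588 higher, 1667 lower) and 84.4% when scaled without the 20 most abundant genes, 15 of them mitochondrial (3464 higher, 639 lower). Scaled without mitochondrial and small RNA genes and the 20 most abundant others, a choice made after seeing the data, it was 65.1% (2153 higher, 1154 lower). Calls numbered 62 without Con-TD F, 90 without Con-TD G, 162 without MCK-TD A and 123 without MCK-TD B, and 25, 30, 77 and 61 of these were among the 3837. The 24 genes named by size then kept 4, 5, 6 and 4 calls.

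Most listed genes of fast fibres, the glycolytic fibres of limb muscle, were lower in MCK-TD. Of 17 fast-fibre contractile genes, 10 fell, 0 rose and 7 were not called, and 13 fell when adjusted over the list alone. The fast-fibre myosin heavy chain Myh1, named after its values were seen, was not called. Atp2a1, the fast-fibre calcium pump, fell from 20946 ± 747 to 6868 ± 565 FPKM, and Myh4, the fastest limb myosin heavy chain, from 5174 ± 786 to 1820 ± 418. Actn3 fell from 3336 ± 322 to 1164 ± 242 FPKM, and Mybpc2, fast myosin-binding protein C, from 1400 ± 244 to 350 ± 112. The median change of the list was -0.57, with camera adjusted p = 5.18e-08 and an adjusted p = 0.653 with an estimated correlation. By fry the list did not pass (fry adjusted p = 0.0524). With median of ratios scaling 14 fell, with quantile normalization 7 and without the 20 most abundant genes 5. Between single MCK-TD and Con-TD libraries the list median ran from -0.72 to -0.45. All calls of single members were lost whichever library was left out, but few genes of any kind were called then. Of 13 slow-fibre contractile genes, 3 rose and 1 fell, with a median change of 0.46. Camera did not tell this list from other genes (adjusted p = 0.728). Its median was 1.04 higher in Con-TD G than in Con-TD F on the log2 scale. Between single MCK-TD and Con-TD libraries it ran from -0.32 to 1.17, so the list was not shown to be unchanged. Atp2a2, the slow-fibre calcium pump, rose from 27.0 ± 13.6 to 96.8 ± 5.19 FPKM, Casq2 from 16.9 ± 2.55 to 64.1 ± 0.338 and Actn2 from 140 ± 50.2 to 409 ± 91.8, whereas Myl3 fell. Of these, Atp2a2 and Casq2 are calcium-handling genes, and the myosin light chain Myl3 was the member that fell. In the same libraries the macrophage markers had a median change of 1.80, and those of endothelial cells and of fibro-adipogenic progenitors had medians of -0.58 and -0.71.

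Of 20 genes of the neuromuscular junction and of denervated muscle, 14 rose and 1 fell (15 and 2 adjusted over the list alone), with a median change of 0.90. With median of ratios scaling, and with quantile normalization, 9 rose and 3 fell. Besides Sln, the largest members were Gadd45a (25.9 ± 5.89 to 183 ± 14.2 FPKM), the adhesion molecule Ncam1 (8.37 ± 2.18 to 53.1 ± 3.43) and Chrng, the fetal subunit of the acetylcholine receptor (0.122 ± 0.0331 to 3.52 ± 0.034). This list had a camera adjusted p = 0.0154, or 0.199 over genes with a mean FPKM of at least 5, and an adjusted p = 0.653 with an estimated correlation. Of 17 neonatal and regenerating-fibre genes, 11 rose and 1 fell, also when adjusted over the list alone, with a median change of 1.60 (11 and 2 with median of ratios scaling, 10 and 2 with quantile normalization). Ankrd1 and Myl4 led this list, with Tnnt2, the cardiac and fetal troponin T (2.61 ± 0.727 to 35.5 ± 4.41 FPKM), and Igfn1 (2.62 ± 0.143 to 35.6 ± 12.9). Its camera adjusted p was 0.00883, or 0.0785 over genes with a mean FPKM of at least 5, and the adjusted p = 0.653 with an estimated correlation. Myh3 and Myh8, the embryonic and perinatal myosin heavy chains of this list, were named after their values were seen. Myh8 fell from 239 ± 24.5 to 113 ± 15.2 FPKM (limma adjusted p = 0.0146), and Myh3 was at 27.8 ± 1.55 and 23.0 ± 1.62 FPKM (limma adjusted p = 0.140). The median of the junction genes ran from 0.85 to 1.07 between single MCK-TD and Con-TD libraries. For the neonatal genes it ran from 1.48 to 1.82. Most calls in both lists were lost when a library was left out, but few genes of any kind were called then. The 2 lists share members. The macrophage marker median of 1.80 lay above both of their medians, which does not tell whether macrophages had a part in these rises.

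Other structural lists changed in both directions. Of 22 excitation-contraction and calcium-handling genes, 5 rose, with Sln, Atp2a2 and Casq2 among them, and 6 fell, with Atp2a1 among them (6 and 7 adjusted over the list alone). Their median change was -0.24 and their mean 0.17. Camera placed the list below other genes (adjusted p = 0.0198), with an adjusted p = 0.653 with an estimated correlation, 0.231 with quantile normalization, 0.0631 on ranks and 0.0618 without Con-TD F. Of 29 sarcomere and Z-disc genes, 9 rose and 7 fell (9 and 8 adjusted over the list alone, but 7 and 10 with median of ratios scaling), and camera gave an adjusted p = 0.265. The actin-filament protein Lmod2 rose from 27.8 ± 8.37 to 282 ± 23.2 FPKM, Myom3 from 5.82 ± 3.42 to 19.7 ± 3.30 and Flnc from 33.0 ± 9.29 to 104 ± 0.627. Of 18 dystrophin-complex and membrane-repair genes, 7 rose and 1 fell on the deposited scale (8 and 2 adjusted over the list alone), with camera adjusted p = 0.596. Their balance depended on scaling, with 3 higher and 4 lower with median of ratios scaling, 4 and 4 with quantile normalization and 8 and 0 when scaled without the 20 most abundant genes. The repair genes Trim72 and Dysf rose to 142 ± 31.3 and 65.5 ± 0.865 FPKM, from 40.1 ± 4.09 and 22.8 ± 1.99, and Anxa2 and Sgcd rose by 1.58 and 1.49 on the log2 scale. Thyroid hormone responsive genes stood lower (7 fell and 2 rose of 15, or 8 and 2 adjusted over the list alone; median change -0.66). Their camera adjusted p was 0.000751, and the adjusted p = 0.653 with an estimated correlation. The thyroid list shares 9 of its 15 genes with other lists, Atp2a1, Atp2a2 and Myh4 included, and its member Thrsp rose from 10.1 ± 3.83 to 38.2 ± 2.66 FPKM.

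Subunits of the proteasome, the complex that degrades ubiquitinated proteins, rose almost as a whole. Of 31 subunit genes 29 rose and 0 fell (30 and 0 adjusted over the list alone), with a median log2 change of 0.86. Psmb5, a catalytic subunit, rose from 92.4 ± 4.73 to 274 ± 3.72 FPKM and Psmd8 from 81.7 ± 2.34 to 231 ± 30.8. Psmd11 rose from 44.0 ± 7.41 to 121 ± 10.0 FPKM, and Psmd14 from 40.7 ± 0.45 to 111 ± 6.24. The list's camera adjusted p was 2.56e-07, and the adjusted p = 0.653 with an estimated correlation. With median of ratios scaling 19 of the 31 were called, all higher, and with quantile normalization 21. The list median ran from 0.76 to 0.97 between single MCK-TD and Con-TD libraries. All calls of single subunits were lost whichever library was left out, but few genes of any kind were called then. Ubiquitin-ligase, autophagy and FoxO atrophy genes did not pass as a list (camera adjusted p = 0.0576), while 14 of 32 rose and 2 fell, also when adjusted over the list alone. Among them the autophagy receptor Sqstm1 rose from 285 ± 5.83 to 1793 ± 249 FPKM, and Eda2r from 1.94 ± 0.8 to 28.0 ± 4.59. The list passed in 7 of 19 alternatives besides the estimated correlation. It was 0.0396 with median of ratios scaling, 0.0190 with quantile normalization, 0.0474 with the scaling chosen after seeing the data, 0.0334 on ranks, 0.0149 without a filter, 0.0493 over genes with a mean FPKM of at least 5 and 0.00468 without Con-TD F, but 0.112 without Con-TD G, 0.136 without MCK-TD A, 0.208 without MCK-TD B and 0.757 with an estimated correlation.

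Heat shock and chaperone genes rose (14 of 22, with 1 lower, or 16 and 1 adjusted over the list alone; median change 0.79). Besides Hspb7, Hspb1 went from 127 ± 19.4 to 971 ± 179 FPKM, Cryab from 769 ± 184 to 3017 ± 124, and the co-chaperone Bag3 from 34.8 ± 2.86 to 167 ± 20.4. The list had camera adjusted p = 0.000751 and an adjusted p = 0.653 with an estimated correlation. Genes of the unfolded-protein response of the endoplasmic reticulum rose in 15 of 23 cases, with 0 lower (20 and 0 adjusted over the list alone), and a median change of 0.79. Among them were Sdf2l1 (2.15 ± 0.641 to 7.43 ± 0.841 FPKM), Manf (28.0 ± 1.13 to 75.6 ± 5.06), the chaperone Canx (25.8 ± 0.323 to 63.9 ± 2.63) and Pdia6 (17.0 ± 1.10 to 42.6 ± 11.1). Their camera adjusted p was 0.000136, and an adjusted p = 0.685 with an estimated correlation. Of 29 genes of the integrated stress response, the program of the transcription factor Atf4, 17 rose and 0 fell (20 and 0 adjusted over the list alone; median change 0.70). Mthfd2, a mitochondrial folate enzyme, rose from 1.25 ± 0.0923 to 23.5 ± 2.36 FPKM, and Psat1, of serine synthesis, from 0.977 ± 0.0375 to 14.2 ± 5.08. The amino acid transporter Slc7a5 rose from 0.406 ± 0.173 to 3.82 ± 0.878 FPKM. Gdf15, a stress-induced hormone, was listed at 0.0353 and 0 in Con-TD F and G, and at 2.85 and 3.96 in MCK-TD A and B. The stress response list had camera adjusted p = 9.00e-04 and an adjusted p = 0.653 with an estimated correlation. Counts of these 3 lists were smaller with median of ratios scaling, and the same again with quantile normalization. Then 10 heat shock genes rose and 1 fell, 11 reticulum genes rose and 0 fell, and 12 stress response genes rose and 0 fell. Between single MCK-TD and Con-TD libraries the heat shock median ran from 0.72 to 0.88 and the reticulum median from 0.67 to 1.01. That of the stress response list ran from 0.75 to 0.90. All or most calls in these lists were lost when a library was left out, but few genes of any kind were called then.

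Antioxidant genes of the transcription factor NRF2 rose in 15 of 22 cases, with 1 lower (0 lower when scaled without the 20 most abundant genes), also when adjusted over the list alone, and their median change was 1.13. Hmox1, heme oxygenase, went from 3.34 ± 1.27 to 33.4 ± 6.01 FPKM, and Srxn1 from 7.90 ± 1.16 to 45.8 ± 1.88. Nqo1 rose from 13.0 ± 1.15 to 50.4 ± 19.5 FPKM and Pgd, of the pentose phosphate pathway, from 5.37 ± 0.950 to 19.5 ± 2.42. The camera adjusted p was 0.00287, and the adjusted p = 0.653 with an estimated correlation. Of 21 targets of p53, 10 rose and 1 fell (12 and 1 adjusted over the list alone), with a median change of 0.81. The cell cycle inhibitor Cdkn1a rose from 20.8 ± 9.21 to 106 ± 1.73 FPKM, and Perp from 0.824 ± 0.0575 to 6.32 ± 2.31. For p53 targets the camera adjusted p was 0.0126, or 0.0785 over genes with a mean FPKM of at least 5, and an adjusted p = 0.670 with an estimated correlation. Medians between single MCK-TD and Con-TD libraries ran from 1.06 to 1.15 for the NRF2 genes and from 0.72 to 0.93 for the p53 targets. All or most calls in both lists were lost when a library was left out, but few genes of any kind were called then. Macrophage markers, with a median change of 1.80, moved in the same direction as these stress lists, and the part of macrophages in these rises was not tested.

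**Figure D2:**
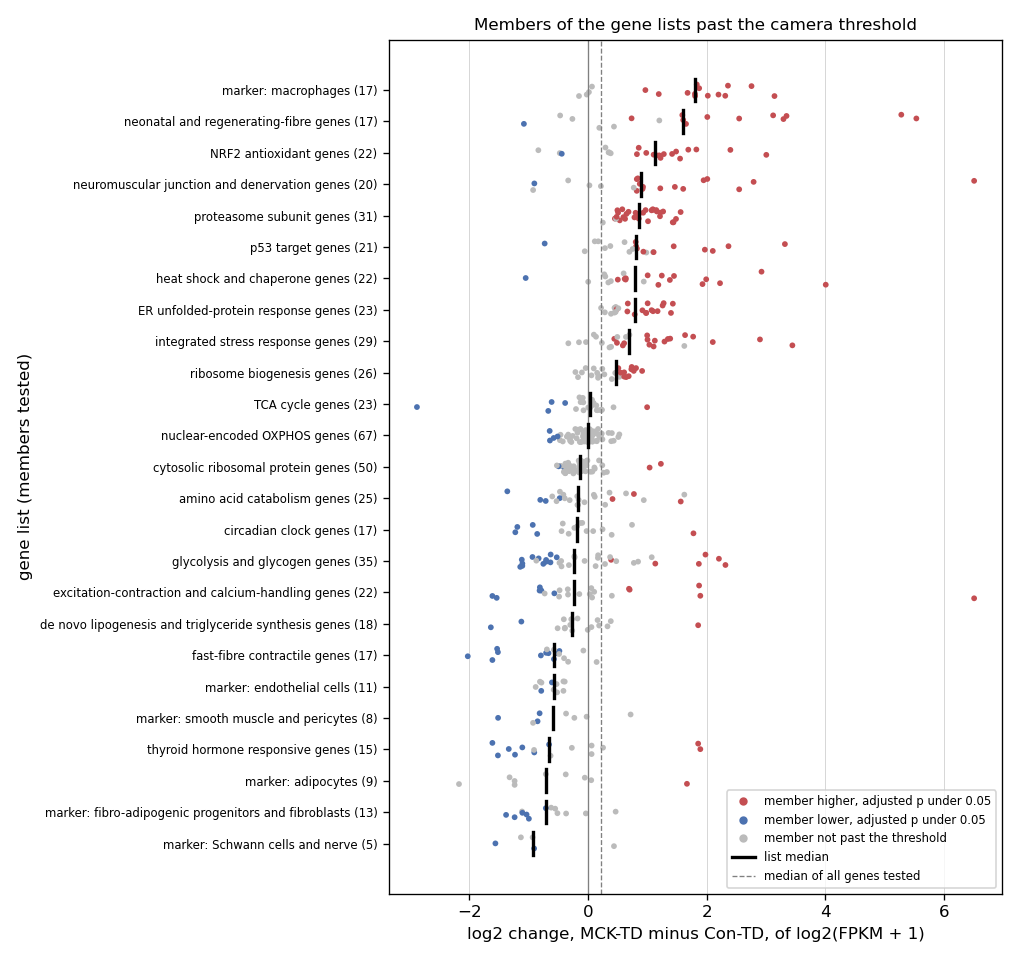
Log2 change (MCK-TD minus Con-TD, of log2(FPKM + 1)) of each tested member of the 25 lists past the camera threshold, 1 point per gene and the list median as a black bar; red and blue points are called higher and lower, and grey points are not called. Medians run from -0.93 for Schwann cell markers to 1.80 for macrophage markers, and the dashed line is the median of all genes, 0.22.

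Genes of energy metabolism changed in both directions. Of 35 glycolysis and glycogen genes, 12 fell and 6 rose (14 and 10 adjusted over the list alone), with a median change of -0.23 and a mean of 0.03. The largest changes were of genes that rose, Gbe1, the glycogen branching enzyme (21.7 ± 6.28 to 111 ± 13.2 FPKM), Hk1, the hexokinase of most tissues (1.59 ± 0.146 to 11.0 ± 2.13), and the transporters Slc2a1 (2.35 ± 0.703 to 12.1 ± 0.472) and Slc16a1 (5.90 ± 1.83 to 24 ± 4.94). Camera placed the list below other genes (adjusted p = 0.00437), with an adjusted p = 0.653 with an estimated correlation and 0.231 with quantile normalization. Of 67 nuclear-encoded genes of oxidative phosphorylation, 4 fell and 0 rose (0 and 0 adjusted over the list alone), namely Ndufs1, Ndufs7, Ndufc1 and Atp5g2, with log2 changes of -0.65, -0.64, -0.58 and -0.51. Their median change was -0.01, with 11 lower calls and a median of -0.26 with median of ratios scaling, 8 and -0.15 with quantile normalization, and 2 lower, 1 higher and 0.07 when scaled without the 20 most abundant genes. Camera placed them below other genes (adjusted p = 0.00497), with an adjusted p = 0.834 with an estimated correlation, 0.181 without Con-TD G and 0.354 without MCK-TD B. Of 23 genes of the TCA cycle and its feeder enzymes, 4 fell, with Pcx, Suclg2 and Idh3b among them, and Mdh1 rose from 439 ± 44.5 to 878 ± 112 FPKM (3 and 1 adjusted over the list alone). Their median change was 0.03 and their mean -0.11. Camera gave an adjusted p = 0.0473 towards lower, an adjusted p = 0.791 with an estimated correlation, 0.157 with quantile normalization, 0.108 when scaled without the 20 most abundant genes, 0.113 without Con-TD G and 0.615 without MCK-TD B. The TCA list passed in 9 of 19 alternatives besides the estimated correlation.

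Lipid, amino acid and nucleotide genes changed in both directions. Of 18 lipogenesis and triglyceride synthesis genes, 2 fell and 1 rose (1 and 1 adjusted over the list alone; median change -0.27), and 3 fell with quantile normalization and 1 when scaled without the 20 most abundant genes. The desaturase Scd1 fell from 15.5 ± 4.68 to 4.20 ± 0.188 FPKM and Fasn, fatty acid synthase, from 11.8 ± 4.25 to 4.76 ± 0.787, whereas Thrsp rose. Camera gave an adjusted p = 0.00883, an adjusted p = 0.653 with an estimated correlation, 0.0705 without Con-TD G and 0.0582 without MCK-TD B. Of 41 genes of fatty acid uptake and oxidation, 9 rose and 4 fell, also when adjusted over the list alone, with camera adjusted p = 0.596. The counts were 6 and 5 with median of ratios scaling, and 5 and 6 with quantile normalization. Plin2, a lipid droplet coat protein, rose from 32.6 ± 5.81 to 246 ± 28.8 FPKM, Fabp3 from 241 ± 74.2 to 1421 ± 324 and the ketone body enzyme Bdh1 from 6.91 ± 1.08 to 41.9 ± 14.1, while Plin4 fell from 29.4 ± 10.4 to 10.2 ± 1.41. Of 25 amino acid catabolism genes, 3 rose and 4 fell (4 and 5 adjusted over the list alone; median change -0.17). Counts were 1 higher and 9 lower both with median of ratios scaling and with quantile normalization (medians -0.41 and -0.44), against 4 and 3 when scaled without the 20 most abundant genes. Camera placed this list below other genes (adjusted p = 0.0198), with an adjusted p = 0.653 with an estimated correlation, 0.112 with quantile normalization and 0.0589 without MCK-TD B. The AMP deaminases moved apart, Ampd3 rising by 1.56 and Ampd1 falling by 1.36 on the log2 scale, from 596 ± 18.9 to 235 ± 53.3 FPKM for Ampd1. Of 15 purine nucleotide and creatine genes, 5 rose, Gatm (1.96 ± 0.0333 to 9.09 ± 1.86 FPKM) and Ckb (2.59 ± 1.26 to 9.98 ± 2.34) among them, and 5 fell (6 and 5 adjusted over the list alone), with camera adjusted p = 0.286. Of 16 cholesterol synthesis genes, 5 rose and 1 fell, Mvd and Insig1 rising by 1.26 and 1.23 on the log2 scale, with camera adjusted p = 0.489 (3 and 1 with quantile normalization). Of 29 genes of mitochondrial biogenesis and translation, 3 rose and 0 fell (2 and 0 adjusted over the list alone), Esrrg from 2.20 ± 0.320 to 9.51 ± 3.51 FPKM and the fission protein Dnm1l from 16.5 ± 0.292 to 34.4 ± 0.831 among them, with camera adjusted p = 0.928. For this list 2 rose and 1 fell with median of ratios scaling, 2 and 2 with quantile normalization, and 5 and 0 when scaled without the 20 most abundant genes. Counts for the cholesterol list were the same when adjusted over the list alone.

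Few cytosolic ribosomal protein genes were called on the deposited scale. Of 50, 2 rose and 2 fell (1 and 0 adjusted over the list alone), and the median change was -0.13, or -0.38, -0.31 and -0.05 with median of ratios, quantile and top-gene scaling. Rps2 rose from 105 ± 1.68 to 248 ± 17.2 FPKM and Rpl3 from 9.54 ± 2.08 to 20.5 ± 2.19, while Rpl5 fell by 0.41 on the log2 scale. These genes have many near-identical pseudogenes, and their values are uncertain. For the ribosomal list the camera adjusted p was 3.03e-05 towards lower and an adjusted p = 0.653 with an estimated correlation, and median of ratios scaling gave 20 lower calls and quantile normalization 14. Of 26 ribosome biogenesis genes, 11 rose and 0 fell (13 and 0 adjusted over the list alone; median change 0.47), with Noc4l, Nop58, Bop1 and Polr1a rising by 0.91, 0.81, 0.77 and 0.74 on the log2 scale. In this list 5 rose and 0 fell with median of ratios scaling (median 0.25), and 4 and 1 with quantile normalization (median 0.20). Their camera adjusted p was 0.0452, and the adjusted p = 0.653 with an estimated correlation. It was 0.155 with median of ratios scaling, 0.215 with quantile normalization, 0.0591 without Con-TD F, 0.125 without Con-TD G and 0.142 without MCK-TD B, and the list passed in 9 of 19 alternatives besides the estimated correlation.

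Of 17 circadian clock genes, 4 fell and 1 rose, also when adjusted over the list alone, with a median change of -0.18. Cry2, a repressor of the clock, rose from 4.40 ± 0.343 to 17.6 ± 2.39 FPKM, while Dbp fell from 48.7 ± 16.5 to 20.2 ± 0.717, Nr1d1 from 64.9 ± 4.47 to 33.8 ± 6.12 and Hlf from 2.20 ± 0.8 to 0.350 ± 0.0765. Camera gave an adjusted p = 0.0154, an adjusted p = 0.670 with an estimated correlation, 0.0535 with median of ratios scaling, 0.0756 with quantile normalization and 0.129 without Con-TD F. The labels give no time of day for the samples. Of 22 muscle growth signalling genes, 2 rose, Igf2 (7.25 ± 0.891 to 31.2 ± 6.88 FPKM) and Igfbp5 (91.5 ± 11.9 to 268 ± 21.3), and 4 fell, with Mstn, encoding myostatin, an inhibitor of muscle growth (29.5 ± 8.63 to 9.97 ± 1.65), and Irs1 among them. Those counts were the same when adjusted over the list alone, and the camera adjusted p was 0.265. Of 14 muscle-secreted factor genes, 3 rose and 2 fell, Il15 falling from 4.10 ± 0.156 to 1.36 ± 0.460 FPKM and Metrnl rising from 3.03 ± 0.962 to 9.47 ± 2.30, with camera adjusted p = 0.333. Of 17 targets of YAP, TAZ and TEAD, 9 rose and 1 fell (9 and 3 adjusted over the list alone), with Ankrd1, Ctgf (9.76 ± 1.9 to 30.4 ± 4.48 FPKM) and Tead4 (0.810 ± 0.236 to 3.83 ± 0.240) among those that rose and camera adjusted p = 0.542. This balance was 7 and 3 with median of ratios scaling, 6 and 4 with quantile normalization and 9 and 0 when scaled without the 20 most abundant genes. Of 19 cell cycle genes, 8 rose and 1 fell, Birc5 (0.335 ± 0.0721 to 3.14 ± 0.510 FPKM) and Mcm6 (0.386 ± 0.177 to 2.8 ± 0.5) rising and Aurka falling (5.78 ± 0.511 to 1.5 ± 0.270), with camera adjusted p = 0.379; 6 rose and 2 fell with median of ratios scaling, and 4 and 3 with quantile normalization.

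Several signalling lists also did not pass as lists. Of 27 immediate early genes, 4 rose and 2 fell, Ier3 rising by 2.06 and Nr4a1 falling by 2.01 on the log2 scale, from 108 ± 11.1 to 26.1 ± 1.05 FPKM for Nr4a1. Counts were even with median of ratios scaling (4 and 4) and with quantile normalization (3 and 3). The camera adjusted p of this list was 0.0530, or 0.00111 without Con-TD G and 0.0134 without MCK-TD A, but 0.577 without Con-TD F and 0.372 without MCK-TD B. It was 0.0467 with a pseudocount of 0.1, 0.0493 over genes with a mean FPKM of at least 5, 0.0348 when scaled without the 20 most abundant genes and 0.0287 over protein-coding symbols, against 0.219 with median of ratios scaling and 0.281 with quantile normalization. Of 26 hypoxia and HIF targets, 8 rose and 2 fell (10 and 2 adjusted over the list alone), Pfkfb3 falling from 37.3 ± 1.31 to 16.7 ± 0.319 FPKM, with camera adjusted p = 0.859. For hypoxia targets 5 rose and 5 fell with median of ratios scaling, and 5 and 4 with quantile normalization. Of 19 glucocorticoid responsive genes, 2 rose, Pik3r1 and Tsc22d3, and the receptor Nr3c1 fell, with log2 changes of 1.08, 0.62 and -0.66 and camera adjusted p = 0.375, from 0.0156 without Con-TD G to 0.501 without MCK-TD B, and 1 higher and 3 lower calls with median of ratios scaling or 1 and 4 with quantile normalization. Of 14 genes of cholinergic, adrenergic and cAMP signalling, 3 rose, Prkar1a and Chrna1 among them, and 2 fell, Nr4a1 and Pde4d, with camera adjusted p = 0.173, from 0.0287 without Con-TD G to 0.407 without MCK-TD A, and 1 higher and 2 lower calls with median of ratios scaling or 1 and 3 with quantile normalization. Of 7 targets of Wnt and Notch, 0 rose and 0 fell by limma's test (camera adjusted p = 0.375). The smallest limma adjusted p among these 7 was 0.150, for Axin2.

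Markers of other cell types moved apart. Of 17 macrophage markers, 13 rose and 0 fell, also when adjusted over the list alone, with a median change of 1.80. Lgals3 rose from 5.42 ± 0.821 to 55.5 ± 0.636 FPKM, Cd68 from 2.12 ± 0.586 to 20 ± 3.37, Lyz2 from 12.7 ± 3.34 to 69.0 ± 13.7 and Trem2 from 0.0746 ± 0.0367 to 4.37 ± 0.836. Camera gave an adjusted p = 0.00165 and an adjusted p = 0.653 with an estimated correlation. Of 13 markers of fibro-adipogenic progenitors and fibroblasts, 6 fell and 0 rose (8 and 0 adjusted over the list alone; median change -0.71), Clec3b from 20.2 ± 1.51 to 7.18 ± 1.23 FPKM and Smoc2 from 53.7 ± 0.600 to 24.4 ± 1.04 among them. Their camera adjusted p was 1.39e-05, and the adjusted p = 0.653 with an estimated correlation. Endothelial markers had a median change of -0.58, and 2 of 11 fell, Tie1 and Tek by 0.79 and 0.61 on the log2 scale (0 adjusted over the list alone, 6 with median of ratios scaling or quantile normalization, 1 when scaled without the 20 most abundant genes). The endothelial list had a camera adjusted p = 4.96e-05 and an adjusted p = 0.653 with an estimated correlation. Of 8 markers of smooth muscle and pericytes, 3 fell and 0 rose, also when adjusted over the list alone, and Rgs5 went from 61.2 ± 7.58 to 21.1 ± 6.19 FPKM. This list had camera adjusted p = 0.00637 and an adjusted p = 0.653 with an estimated correlation. Of 5 Schwann cell markers, 2 fell, Pmp22 from 25.7 ± 4.50 to 13.2 ± 2.06 FPKM among them (4 adjusted over the list alone, 4 with quantile normalization), with camera adjusted p = 0.0126, 0.0535 with median of ratios scaling and 0.0573 with quantile normalization. The adjusted p = 0.653 with an estimated correlation held for these markers as well. Medians between single MCK-TD and Con-TD libraries ran from 1.52 to 2.09 for macrophage markers and from -1.02 to -0.53 for fibroblast markers. They ran from -0.81 to -0.30 for endothelial, -0.74 to -0.41 for smooth muscle and -1.44 to -0.56 for Schwann cell markers. All calls in these lists, or most for macrophages, were lost when a library was left out, but few genes of any kind were called then.

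Adipocyte markers had a median change of -0.71, but of 9 only Cidea was called, and it rose from 0.269 ± 0.0483 to 3.03 ± 0.118 FPKM. Camera gave an adjusted p = 0.0449 towards lower and an adjusted p = 0.653 with an estimated correlation. The call was lost without Con-TD G (0.0711), without MCK-TD A (0.0694), without MCK-TD B (0.208) and with median of ratios scaling (0.174) or quantile normalization (0.3), and it held in 9 of 19 alternatives besides the estimated correlation. Of 8 tenocyte markers, 3 rose, Scx (2.26 ± 0.107 to 15.6 ± 1.43 FPKM), Thbs4 (15.9 ± 2.8 to 78.1 ± 1.68) and Prg4, and Kera fell, with camera adjusted p = 0.928. Of 39 collagen and extracellular matrix genes, 12 rose and 4 fell (12 and 6 adjusted over the list alone), with camera adjusted p = 0.538. Those counts became 9 and 6 with median of ratios scaling, 8 and 6 with quantile normalization, and 12 and 1 when scaled without the 20 most abundant genes. Besides Lox, those that rose most were Timp1 (0.655 ± 0.375 to 18.8 ± 0.721 FPKM), Postn (6.46 ± 2.49 to 83.8 ± 20.6) and Thbs4. Of 7 satellite cell markers, 2 rose, Itga7 (10.5 ± 1.62 to 30.0 ± 4.07 FPKM) and Sdc4 (11.4 ± 1.62 to 26.9 ± 3.27), with camera adjusted p = 0.402. Of 7 erythroid markers only Bpgm was called, and it fell from 43.7 ± 1.5 to 15.3 ± 0.733 FPKM (camera adjusted p = 0.118, from 0.00149 without Con-TD F to 0.885 without Con-TD G). None of 3 neutrophil markers was called by limma (camera adjusted p = 0.591), and the smallest limma adjusted p among them was 0.600, for Retnlg. Of 22 inflammatory cytokine and acute-phase genes, 5 rose and 2 fell, Spp1 rising from 2.06 ± 1.06 to 32.0 ± 0.663 FPKM and Ccl2 from 1.31 ± 0.548 to 8.02 ± 1.95, with camera adjusted p = 0.333, from 0.0427 without Con-TD F to 0.762 without Con-TD G (6 and 1 when scaled without the 20 most abundant genes). Of 24 interferon response genes, 3 rose and 1 fell (1 and 1 adjusted over the list alone, and 1 and 1 with median of ratios scaling or quantile normalization), Igtp rising from 4.89 ± 0.297 to 47.4 ± 13.8 FPKM and Gbp7 falling from 3.13 ± 0.562 to 1.03 ± 0.0185, with camera adjusted p = 0.790.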

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

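The alternatives protein-coding symbols only, rows without a 0, 1 row per symbol and a scaling without mitochondrial and small RNA genes and the 20 most abundant others were chosen after seeing the data. No paired analysis was possible because the labels give the groups no shared replicate numbers. The planned count-based alternatives, DESeq2 and no filter on low counts, were not run, since the table holds FPKM. Leaving out each library in turn leaves a single sample in 1 group, assumed to vary like the other group. Calls then ranged from 62 to 162, with 12 to 154 higher and 8 to 68 lower, 4 to 6 of the 24 genes named by size were called, and 19 to 25 lists. These fits have fewer samples. Lower calls outnumbered higher calls when a Con-TD library was left out, and the reverse held when an MCK-TD library was left out. Without a filter on low values 2043 genes were called (1668 higher, 375 lower), since many more rows were tested. Median of ratios scaling gave 1833 higher and 1510 lower calls, and quantile normalization 1588 and 1667, with 8 lists lower. At an adjusted p below 0.1, 1304 genes were lower. A fold of at least 2 with groups that do not overlap, with no test, gave 2456 genes (1947 higher, 509 lower). With an estimated inter-gene correlation, 0 lists passed by camera (0 higher, 0 lower; smallest adjusted p 0.653). The estimate rests on 2 residual degrees of freedom. A simulated list passed with it (camera adjusted p 0.00973), but its 20 members all changed by 1 with independent errors. That pass does not measure the power for the real lists. Lists with slightly negative estimated correlations (-0.05 for junction genes, -0.04 for heat shock genes) had the same camera adjusted p of 0.653. The value alone therefore does not show that members of a list are correlated. The estimates themselves differed between lists. They were far above the preset 0.01 for fast-fibre (0.38), proteasome (0.48), reticulum (0.71) and oxidative phosphorylation genes (0.80). At camera's preset correlation 25 lists passed. By fry, which tests whether members move one way without comparing them with other genes, 13 passed, 2 of them lower. These 2 were glycolysis and glycogen genes (fry adjusted p 0.0405) and thyroid hormone responsive genes (0.0437). Fast-fibre genes (0.0524) and ribosomal protein genes (0.303) did not pass by fry. Nor did fibroblast (0.101), endothelial (0.165), smooth muscle (0.171) and Schwann cell markers (0.121). Of lists that camera placed higher, p53 targets (0.0524) and reticulum genes (0.0537) did not pass by fry. Fry and camera differed in direction for 11 lists, 9 of them past the threshold by neither test. The other 2 were purine nucleotide and creatine genes (fry adjusted p 0.0137, higher) and adipocyte markers (fry adjusted p 0.662, higher); the cause was not tested. Pseudocounts, a mean FPKM of at least 5, variance models and the alternatives added later kept all counts within 1.5 times of the main ones. What depth limits cannot be given, since the absolute depth is unknown. At 2 libraries per group, 36% of simulated changes of 0.5 were called. That simulation had independent errors and few changed genes, so the share need not hold for the real data.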

Other observations

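Gene families formed by symbol stem, with at least 8 members tested, were compared after the lists had been seen, and the genes named here were chosen after their values were seen. Of 157 families, 7 passed camera with the preset correlation, and 0 passed with an estimated correlation (smallest adjusted p 0.907). Of 8 Serpinb genes, intracellular serine protease inhibitors, 7 rose and 0 fell (median change 1.81, camera adjusted p = 0.00654, adjusted p = 0.907 with an estimated correlation). Besides Serpinb1a, Serpinb6a rose from 75.4 ± 9.42 to 352 ± 119 FPKM and Serpinb6b from 1.13 ± 0.135 to 13.4 ± 0.338 (mean ± SD, 2 libraries per group), although these close paralogs share fragments. Of 8 microtubule-associated Mtap genes, 6 rose and 0 fell (median 1.09, camera adjusted p = 0.0403, adjusted p = 0.907 with an estimated correlation). Mtap1a rose from 0.723 ± 0.343 to 19.5 ± 2.64 FPKM, Mtap1b from 0.683 ± 0.325 to 17.1 ± 4.30 and Mtap4 from 94.8 ± 8.81 to 234 ± 31.2. Medians of these families kept their sign under each of the 3 planned scalings.

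Of 12 Myh genes, 6 fell and 2 rose (median -0.76, camera adjusted p = 0.0403, adjusted p = 0.907 with an estimated correlation). Myh13, the extraocular myosin heavy chain, fell from 38.3 ± 4.53 to 19.5 ± 0.706 FPKM, and the nonmuscle chain Myh14 rose from 6.43 ± 0.900 to 11.6 ± 0.447. Myh1, a fast-fibre myosin heavy chain, was at 1284 ± 265 FPKM in Con-TD and 1419 ± 285 in MCK-TD (limma adjusted p = 0.645). Of 8 Mup genes 3 fell (median -1.67, camera adjusted p = 0.000270, adjusted p = 0.907 with an estimated correlation), at low levels and with near-identical copies. The other families that passed were Rpl and Rps, which hold pseudogenes, and Psmd. Fgf21, a stress hormone too low to be tested, was listed at 0 in both Con-TD libraries and at 0.779 and 2.60 in MCK-TD A and B. Among mitochondrial genes, mt-Nd4 was at 28927 and 30854 FPKM in Con-TD and mt-Nd4l at 20191 and 19702, and both were listed at 0 in both MCK-TD libraries. Neighbouring mitochondrial genes showed no such step, as mt-Nd5 was at 9530 and 8318 FPKM in Con-TD and 9341 and 7880 in MCK-TD. Xist was at 17.1, 20.5, 10.1 and 12.1 FPKM in Con-TD F, Con-TD G, MCK-TD A and MCK-TD B, and Ddx3y was at most 0.227 in any of them.

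The tests of scaling and of the share of muscle fibres, below, were chosen only after the result was seen. Calls on the deposited scale were 79.0% higher, and MCK-TD had less of its FPKM outside mitochondrial and small RNA genes in the 20 most abundant of them (36.0% and 38.3%, against 48.3% and 43.8% in Con-TD). With libraries scaled by the median of ratios 54.8% of calls were higher, but that scaling brings the median change from 0.22 to 0.01 and so gives a near-even balance whatever the cause. Scaled on the sum without mitochondrial and small RNA genes and the 20 most abundant others, 65.1% of calls were higher and the median change was 0.09, nearer to an even balance but not at it. How much of the imbalance is scale and how much a rise of many genes stays open, as total RNA was not measured.

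The lower level of fast-fibre contractile genes may have come from a smaller share of muscle fibres. If the other cell types kept their proportions to one another, their markers would then rise alike. These moved apart. The endothelial median minus that of all genes was -0.80 on the log2 scale (spread 0.33 between libraries of a group). For macrophages the difference was 1.59 (spread 0.29). This argues only against a smaller fibre share with the other cells in unchanged proportions. The marker medians cannot exclude a smaller share in which the other cells shifted as well. The trend of the changes with transcript length was small, shifting the middle 90% of genes by -0.05 to 0.03, and the median of the 17 genes relative to all genes with a length was -0.83 before and -0.85 after its removal (spread 0.28), which argues against length as the whole cause. A smaller fibre share alone would also lower other fibre genes. Of 29 sarcomere and Z-disc genes, 9 rose and 7 fell. Their median was 0.11 (0.02 to 0.11 between single MCK-TD and Con-TD libraries), against -0.57 (-0.72 to -0.45) for the fast-fibre list. With median of ratios scaling the medians were -0.15 and -0.83. These values argue against a smaller fibre share as the whole cause. A change in the fibres themselves remains a hypothesis. These data leave it untested against a shift in cell shares that includes the types of fibre, an unrecorded batch or a difference in the part of the muscle taken.

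The rise of the proteasome subunits could reflect transcript length, or proteasomes of the immune type brought by infiltrating cells or interferon. The small length trend given above left their median relative to all genes with a length at 0.60 before and 0.60 after its removal (spread 0.19), which argues against length as the whole cause. The immune-type subunits Psmb8, Psmb9 and Psmb10, with the activators Psme1 and Psme2, had a median change of 0.01, which is -0.85 against the 31 listed subunits (spread 0.40). These 5 genes moved apart. Psmb10 and Psme2 changed by 0.53 and 0.65, and Psme1 by -0.46. Psmb8 and Psmb9, at -0.05 and 0.01, reached at most 3.15 FPKM in any library. Each of the 5 lay below the median of the listed subunits, 0.86. Scaling does not remove the rise either, as 19 of 31 were called with median of ratios scaling. Macrophages, whose markers rose, carry standard proteasomes too, and their part in the rise was not measured.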
